A study of Rattus norvegicus with 9 samples.

How the data were processed

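RNA of rat gastric mucosa was extracted with TRIzol, messenger RNA was selected with oligo(dT) beads and fragmented, and PCR-amplified libraries were made from randomly primed cDNA, per the labels' protocols. The labels give 3 groups (Control, Model and LPY) with 3 libraries each. A single table of the series was used, with 23093 Ensembl rat genes and their symbols, 1828 of them without a symbol and 194 symbols on more than 1 gene. For each library the authors deposited an estimated count per gene, not normalized, in which 8.06% to 8.82% of genes held a value that was not whole. For each library the authors also deposited TPM, that is, counts scaled by transcript length and by the library's total, per the file headers. DESeq2 is the only tool named, without version or role, per the submitters' processing notes. The aligner, the quantifier, the genome build, the annotation release and the strand setting are not given in the sources used here, so no coordinates are reported and genes that overlap or share reads with similar copies are uncertain. The table held 0 columns of other series. A table of RefSeq genes was not used here, as the symbols came from the deposited table itself.

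Estimated counts were rounded to whole numbers, and genes with too few counts were removed with filterByExpr of edgeR 4.0.16 (R 4.3.3), leaving 14211 genes. Libraries were scaled with TMM (factors 0.979 to 1.03), all 9 libraries were fitted in a model with 1 mean per group and no covariate, and each pair of groups was compared with the quasi-likelihood F test of edgeR (glmQLFit, glmQLFTest), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 without a minimum fold. Rose, fell and called refer to this test. The comparisons, the main tests, the 33 gene lists described below, the rule for named genes and most alternatives were set before the data were examined. Limma on log2(TPM + 1), the counts at 2-fold or more, glmTreat, the offset for effective length and the medians of the called lists under the alternatives were added after seeing the data. The pseudocounts of 0.5 and 0.1 were planned and were run with limma on TPM, because the count test has none. Standard errors of log2 fold changes were taken as the fold change over the square root of its F statistic. Levels are TMM-scaled CPM, counts over the scaled library size. Total counts were 14509583 to 22974573 per library, at which 3 counts equal 0.132 to 0.209 CPM. Where a group had no count, the fold is a bound computed with 3 counts over the whole group. With 1 to 3 counts, the ratio is given with an exact 95% interval for counts.

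In all, 33 gene lists written from textbook knowledge were used: gastric cell types (parietal, chief, surface mucous, mucous neck with metaplasia and progenitors, enteroendocrine), other tissues and cell types (squamous forestomach epithelium, smooth muscle, skeletal muscle, adipocytes, intestinal epithelium, pancreatic acini, endothelium, erythrocytes, fibroblasts with extracellular matrix, enteric neurons and glia), immune cells and signals (cytokines and neutrophil products, toll-like receptors with NF-kappaB, interleukin 17, interferon, antigen presentation, T and natural killer cells, B and plasma cells, macrophages, mast cells and eosinophils) and processes (tight junctions and adhesion, the cell cycle, apoptosis and p53, the unfolded protein response, xenobiotic and antioxidant response, nuclear electron transport, the mitochondrial genome, immediate early and heat shock genes). A list of sex-linked genes had 3 of its 6 genes measured, under the minimum of 5, and was not tested. A further 4 lists (circadian clock, mesothelium, hepatocytes and glucocorticoid-responsive genes) were chosen after results had been seen and adjusted among themselves. Lists were tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01, adjusted over the 32 lists fixed before, and again with the correlation estimated from the data and with fry. The number of members called is given over all genes and adjusted over the list alone, that is, with the adjustment over the members of that list.

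Named genes are, per comparison, the 12 highest and 12 lowest fold changes among called genes with a symbol, a mean of at least 1 TPM or 10 counts in the higher group and no overlap between the replicates of the groups; up to 4 members of smallest p of each called list; and Il1b, Tnf, Il6, Cxcl1, Ptgs2, Nos2, Muc5ac, Tff1, Tff2, Atp4a, Atp4b, Pgc, Gast, Ocln and Tjp1. Genes outside this rule, such as list members that moved against their list, were chosen after their values were seen. Fold changes of 2 comparisons were correlated across genes, with 20 simulations of unchanged groups giving the value that shared libraries produce.

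The alternatives were limma on log2(TPM + a pseudocount of 1, 0.5 or 0.1) for genes with at least 1 TPM in at least 3 libraries, no filter on low counts, a mean count of at least 50, DESeq2 size factors, quantile normalization (voom), a fit of the compared groups alone, the DESeq2 1.42.0 Wald test, limma (voom) with array weights, limma on log2 CPM without trend and robust options, the replicate number as a block, each library left out in turn, an estimated inter-gene correlation, glmTreat against a 2-fold change, and an offset for effective length. Robust fits used statmod 1.5.0, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

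The test was tested on simulated data drawn from the real genes' means and library sizes, with genes changed by known folds in each comparison. In Model against Control (13979 genes) 20% of genes changed 1.2-fold, 53.7% of those changed 1.5-fold and 76.9% of those changed 2-fold were called, in LPY against Model (14015 genes) 23.9%, 59.7% and 76.6%, and in LPY against Control (13985 genes) 26.6%, 57.6% and 77.3%. Of all calls, 3.45%, 3.28% and 4.80% were false. These rates come from a single simulated data set per comparison, with the variance fixed at 3.83 times the mean. At each fold 64 to 67 genes were changed, far fewer than were called in the real data. No further variation between animals was simulated, so the rates do not carry over to separate animals.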

Results

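RNA from the gastric mucosa of Wistar rats was sequenced in 9 libraries, 3 from each of 3 groups. Control rats were left without any treatment, Model rats had gastritis brought on by Helicobacter pylori, a bacterium that colonizes the stomach, and LPY rats were rats of the gastritis model that were given Jiawei Lianpu Yin, a Chinese herbal decoction, into the stomach. Total counts were 15291184, 14699275 and 15522406 in Control replicates 1, 2 and 3, 22974573, 14853048 and 20204472 in Model, and 15068595, 16390986 and 14509583 in LPY. Of 23093 genes listed, 14211 had enough counts to be tested. Pgc (ENSRNOG00000014492), which encodes the pepsinogen precursor of the gastric protease gastricsin, took 17.8% ± 0.0595 (SD, n = 3) of all counts in Control, 7.67% ± 0.116 in Model and 14.8% ± 0.105 in LPY. The 13 genes of the mitochondrial genome took 12.2% ± 0.128, 21.4% ± 0.268 and 18.6% ± 0.351. The first principal component held 52.0% of the variance, with Control and Model at its ends and LPY between them. The second held 25.8% and set LPY apart from the other groups. Log counts of libraries of the same group correlated at r = 0.979 to 0.982 (9 pairs) and those of different groups at 0.905 to 0.937 (27 pairs). Libraries of the same group differed by more than counting noise, with a chi-square per degree of freedom of 3.56 to 4.88, so none were merged as 1 library deposited again, although repeat libraries made from shared RNA can also differ by more than counting noise. The labels do not say whether the libraries of a group came from separate animals. All p-values thus measure only the spread between these samples, which may be technical. The edgeR test estimates that spread for each gene partly from the other genes. Standard errors and p-values can therefore be smaller than a gene's own libraries would give, as for Pgc in Model against Control. Below, a value after ± is the standard error of a log2 fold change or the SD over 3 libraries of CPM, the count scaled to a common library size.

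The comparison of Model with Control asked how the infected stomach differed from the untouched one. In Model the digestive enzymes of chief cells, the enzyme-secreting cells of the gastric glands, were lower and the contractile genes of smooth muscle were higher. Pgc fell from 172530 ± 464 to 77920 ± 1721 CPM (log2 fold change -1.15 ± 0.0081, adjusted p = 7.34e-48), and Cym (ENSRNOG00000018236), which encodes the milk-clotting protease chymosin, fell from 3678 ± 58 to 6.1 ± 0.351 CPM (-9.23 ± 0.041). Chga (ENSRNOG00000052549), which encodes the hormone-granule protein chromogranin A, fell from 715 ± 5.96 to 175 ± 2.38 CPM (-2.03 ± 0.033). Actg2 (ENSRNOG00000029401), the enteric smooth muscle actin, rose from 2856 ± 39.5 to 7885 ± 41.5 CPM (1.47 ± 0.015). Hspa1b (ENSRNOG00000050647), an inducible heat shock protein, rose from 90.6 ± 3.39 to 520.1 ± 12.3 CPM (2.52 ± 0.044), although reads of Hspa1b and its near-identical copy Hspa1a can be assigned to either gene.

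In total 8609 genes passed the edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, of which 4181 were higher and 4428 lower in Model. At a fold change of 2 or more, 562 were higher and 2157 lower. With quantile normalization these splits were 5261 higher and 3781 lower, and 1063 and 1609 at 2-fold or more, and limma on log2(TPM + 1) split all calls into 2990 higher and 4714 lower. The replicates of the 2 groups did not overlap for 64.4% of tested genes. Chance gives 10% only if the libraries are independent samples, which the labels do not say. Among the genes with the highest fold changes were Aldh1a7 (ENSRNOG00000017878), an aldehyde dehydrogenase, at 143 ± 15.6 against 4.47 ± 1.58 CPM (4.99 ± 0.11), and Scd (ENSRNOG00000013552), a fatty acid desaturase, at 384 ± 9 against 37.8 ± 2.84 CPM (3.34 ± 0.046). The galectin gene Lgals5 rose by 3.56 ± 0.18 and the heart myosin gene Myh6 (ENSRNOG00000025757) by 5.13 ± 0.43. The proton pump subunit gene Atp6v0a4 rose by 4.73 ± 0.44 and the glucagon-like peptide 2 receptor gene Glp2r by 4.58 ± 0.42. Stmnd1, Rpl39l, Cdnf and Nkx3-2 rose by 4.17, 3.41, 3.39 and 3.31, Rpl39l by 5.15 with quantile normalization. On the log2(TPM + 1) scale, which shrinks changes of low genes, Myh6, Atp6v0a4, Glp2r, Stmnd1 and Rpl39l were at 1.46, 2.13, 2.56, 1.44 and 1.22. Togaram2 was 25.5-fold higher (95% counting interval 8.44 to 126). Tex52 rose by 4.74 ± 0.98, or 8.66 without Control replicate 3. Its call was lost with the DESeq2 Wald test (adjusted p = 0.0971; 5.42e-11 to 0.0971 over its alternatives). The genes with the lowest fold changes were listed at 0 in all Model libraries or nearly so. Krt13 (ENSRNOG00000014070), a keratin of stratified squamous epithelium, was at 29.6 ± 0.998 CPM in Control and at least 565-fold lower in Model. Serpinb3a, Clca4, Mt4 and Sprr3 were at least 444, 351, 315 and 292-fold lower. S100g, Gsta5, C18h5orf46 and the intestinal apolipoprotein gene Apoa4 were at least 274, 235, 206 and 194-fold lower. The developmental skeletal myosin gene Myh8 was 5494-fold lower (95% counting interval 985 to 217033). The symbol S100a7l2 stands for a pair of genes with identical fits, each at least 575-fold lower, whose counts are uncertain because their reads can be assigned to either. These lower bounds set a group at 0 to 3 counts over its libraries, and like the intervals they cover counting error only, because PCR-amplified reads without molecular identifiers are not independent molecules.

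**Figure D1:**
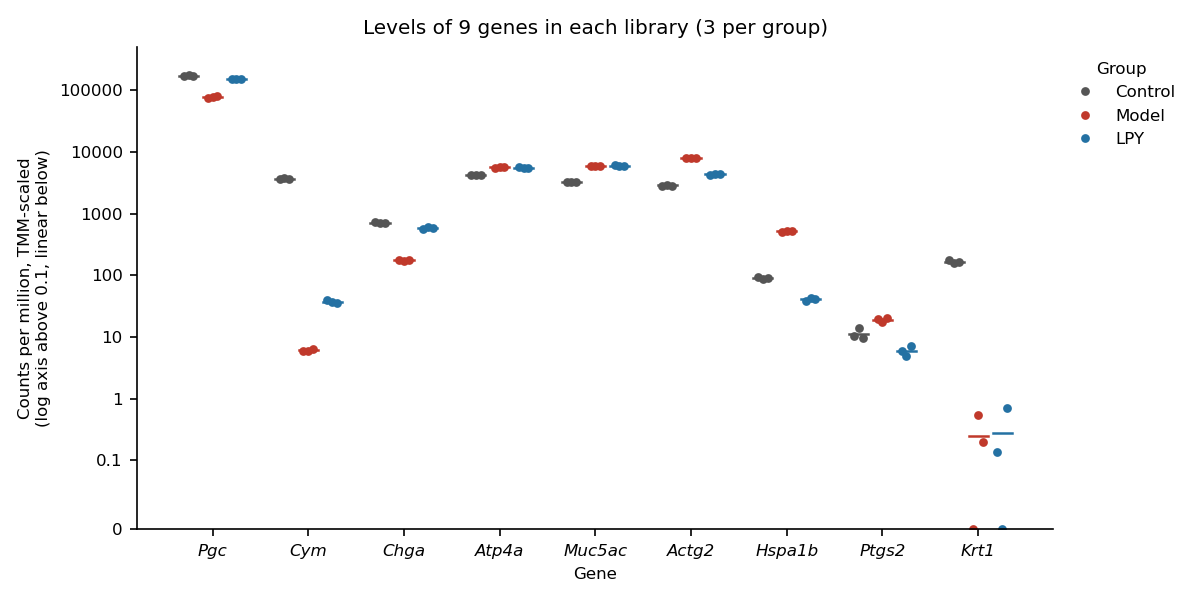
Levels of 9 genes in each library, with the TMM-scaled CPM on an axis that is logarithmic above 0.1 and linear below, 1 point per library and a line at each group's mean (Control grey, Model red, LPY blue). Cym was at 6.10 CPM in Model, 37.6 in LPY and 3678 in Control, Hspa1b was highest in Model at 520.1 CPM, Krt1 was at 167 CPM in Control and under 1 in every Model and LPY library, and Atp4a was higher in Model than in Control by 0.42 on the log2 scale but lower with quantile normalization (-0.13).

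Lists of genes fixed before the data were examined were tested with camera, which compares a list with all other genes, and 16 of 32 were called in Model against Control. Of 13 chief cell markers 12 fell and 1 rose (13 adjusted over the list alone; median log2 fold change -1.15, camera adjusted p = 6.41e-46). The camera adjusted p was 0.00233 with an estimated correlation, which was 0.188. Besides Pgc and Cym these included the chitinase gene Chia (-3.02 ± 0.029) and Cblif, which encodes intrinsic factor (-2.12 ± 0.026). The riser was Nkx6-3 (1.37 ± 0.12), a transcription factor gene of the stomach. Here and below, list members that moved against their list were picked after their values were seen. Of 17 enteroendocrine markers 12 fell and none rose (12 adjusted over the list alone). Their median was -1.12 (adjusted p = 4.86e-13). Fallers included the somatostatin gene Sst (-1.96 ± 0.053), the vesicular amine transporter gene Slc18a2 (-3.84 ± 0.11) and Chgb (-2.44 ± 0.083). The median was -1.78 without a filter on low counts. Of 20 genes of parietal cells, which secrete acid, 15 fell and 4 rose (19 adjusted over the list alone). Their median was -0.50 (adjusted p = 0.0034). Aqp4, a water channel (-2.23 ± 0.052), Esrrg, a nuclear receptor (-2.01 ± 0.08), and Kcnj15, a potassium channel (-1.02 ± 0.054), fell. The proton pump genes Atp4a (ENSRNOG00000020985; 0.42 ± 0.015) and Atp4b (ENSRNOG00000018543; 0.32 ± 0.017) rose, but were lower with quantile normalization (-0.13 and -0.46), and Atp4b was at 0.20 on the log2(TPM + 1) scale. Slc4a2 and Ezr also rose. Of 17 surface mucous cell markers 9 rose and 6 fell (15 adjusted over the list alone). Their median was 0.41 (adjusted p = 0.0151), but the adjusted p was 0.0662 with an estimated correlation. With quantile normalization the test turned downward (median 0.095, adjusted p = 0.535), and the call was lost in 7 more of 21 alternatives (adjusted p 0.0101 to 0.535), among them a replicate block (0.121) and limma on log2(TPM + 1), where the median was 0.15. The gel-forming mucin gene Muc5ac (ENSRNOG00000055996; 0.87 ± 0.015) and the trefoil factor gene Tff1 (ENSRNOG00000001164; 1.00 ± 0.018) rose, by 0.32 and 0.42 with quantile normalization. The trefoil factor gene Tff2 (0.88 ± 0.028), of the mucous neck list, also rose. Gkn2, a secreted gastrokine, rose by 0.41 ± 0.016 but was lower with quantile normalization (-0.38). The mucous neck, metaplasia and progenitor markers were not called, with 6 rising and 8 falling of 16 (14 adjusted over the list alone). Their median was -0.29 (adjusted p = 0.458).

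All 16 smooth muscle genes rose (16 adjusted over the list alone). Their median was 1.15 (adjusted p = 1.61e-57). Risers included the myosin gene Myh11 (1.04 ± 0.014) and Tagln (1.09 ± 0.015). The list summed to 23649 CPM in Control and 53857 in Model. With quantile normalization Myh11 and Tagln rose by 0.64 and 0.52. Of 14 adipocyte genes 12 rose and 1 fell (13 adjusted over the list alone). Their median was 1.04 (adjusted p = 4.34e-06). The fatty acid carrier gene Fabp4 (1.27 ± 0.044) and the adipokine gene Adipoq (1.34 ± 0.065) rose, and the lipoprotein lipase gene Lpl fell (-0.97 ± 0.036). Of 24 genes of squamous forestomach epithelium, the keratinized lining of the upper rat stomach, 22 fell (22 adjusted over the list alone). Their median was -6.16, or -5.03 with genes at 0 set to their bound (adjusted p = 2.92e-19). Their sum was 678 CPM in Control and 55.2 in Model, with Krt10 at -6.03 ± 0.11 and Krt1 at -9.58 ± 0.20. Of 14 skeletal muscle genes 10 fell and 2 rose (12 adjusted over the list alone). Their median was -4.63 (adjusted p = 4.05e-09). The actin gene Acta1 (-3.33 ± 0.078) and the nebulin gene Neb (-5.28 ± 0.24) were among the genes that fell, and Tnnc2 (0.79 ± 0.091) and Ckm (0.33 ± 0.074) rose. On the log2(TPM + 1) scale the medians of the squamous and skeletal lists were -1.79 and -1.94, and Neb was at -1.60. Of 17 intestinal epithelial genes 16 fell and the chloride channel regulator gene Clca1 rose (2.81 ± 0.052; 17 adjusted over the list alone). Their median was -3.37 (adjusted p = 4.09e-07), and the antimicrobial lectin gene Reg3g fell (-3.37 ± 0.14). Of 17 pancreatic acinar genes 15 fell and Cela1 and Ctrl rose (17 adjusted over the list alone). Their median was -1.65 (adjusted p = 1.59e-06), with the chymotrypsinogen gene Ctrb1 at -3.51 ± 0.089 and the lipase gene Cel at -3.26 ± 0.12. The median was -0.99 among genes with a mean count of at least 50. The endothelial list was not called (1 rose and 8 fell of 12, 9 adjusted over the list alone). Its median was -0.60 (adjusted p = 0.0517). The same held for erythrocyte genes (0 rose and 2 fell of 6, 2 adjusted over the list alone; -0.43, 0.467), extracellular matrix and fibroblast genes (8 and 5 of 17, 14 adjusted over the list alone; -0.015, 0.458) and enteric neurons and glia (3 and 7 of 16, 10 adjusted over the list alone; -0.27, 0.911).

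Stress and energy genes also differed between Model and Control. Of 17 immediate early and heat shock genes 13 rose and 1 fell (15 adjusted over the list alone), with the highest member at 7.81. Their median was 0.64 (adjusted p = 5.46e-08), with the transcription factor gene Jun at 0.94 ± 0.046, Ier3 at 1.34 ± 0.069 and Klf4 falling (-0.20 ± 0.047). Of 20 genes of the unfolded protein response 13 fell and 2, Calr and Manf, rose (15 adjusted over the list alone). Their median was -0.60 (adjusted p = 6.47e-07). The chaperone genes of the endoplasmic reticulum Hsp90b1 (-1.65 ± 0.029), Hspa5 (-1.17 ± 0.03) and Canx (-0.75 ± 0.037) fell. Of 31 nuclear genes of mitochondrial electron transport 25 rose and 3 fell (28 adjusted over the list alone). Their median was 0.38 (adjusted p = 2.83e-08), with Cox4i1 at 0.65 ± 0.03 and Atp5f1b at 0.68 ± 0.019 (0.17 with quantile normalization). Of the 13 genes of the mitochondrial genome, whose counts can be shared with nuclear copies, 11 rose and Mt-nd3 fell (-0.22 ± 0.028; 12 adjusted over the list alone). Their median was 0.47 (adjusted p = 2.45e-14), but the adjusted p was 0.0662 with an estimated correlation. It was 0.0578 with quantile normalization, where the median was 0.059 (adjusted p 1.62e-18 to 0.0662 over all alternatives). Mt-co1 (ENSRNOG00000034234), a cytochrome oxidase subunit, rose by 1.17 ± 0.0089 and Mt-nd1 by 1.37 ± 0.02 (0.86 with quantile normalization). Of 22 cell cycle genes 15 rose, such as Rrm2 (1.47 ± 0.11) and Cdc20 (1.77 ± 0.18), and 4 fell, namely Kif11, Mki67 (-0.38 ± 0.089), Bub1 and Pcna (19 adjusted over the list alone). Their median was 0.83 (adjusted p = 0.0131), and the adjusted p was 0.0912 with an estimated correlation (0.000945 to 0.0912 over its alternatives).

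Of 13 measured cytokine and neutrophil genes 4 rose and 2 fell (6 adjusted over the list alone) and the list was not called (median -0.28, adjusted p = 0.78). Ptgs2 (ENSRNOG00000002525), the inducible cyclooxygenase, rose from 11.3 ± 2.25 to 19.1 ± 1.56 CPM (0.76 ± 0.16), and Tnfaip3, Mpo and Lcn2 also rose. Nfkbia and Il1b (ENSRNOG00000004649; -1.56 ± 0.60, adjusted p = 0.0236) fell, but the Il1b call was lost in 6 of 20 alternatives (adjusted p 0.013 to 0.286). Il1b was at -0.82 on the log2(TPM + 1) scale. The alternatives that lost it were quantile normalization (-0.70), limma without trend, and leaving out Control replicate 1 (adjusted p = 0.106) or 2 (0.107) or Model replicate 1 (0.0795) or 3 (0.0754). Cxcl1 was at -1.09 ± 0.90 (adjusted p = 0.302), and Tnf, Il6 and Nos2, with at most 5, 3 and 24 counts in any library, were removed by the filter on low counts. Without that filter they were at 0.038 ± 1.62, -2.73 ± 2.35 and -2.04 ± 1.11 (adjusted p = 1, 0.354 and 0.118). Of 10 mast cell and eosinophil markers 9 fell (9 adjusted over the list alone). Their median was -2.23 (adjusted p = 0.00914), and the adjusted p was 0.0866 with an estimated correlation (0.000905 to 0.0866 over its alternatives). Fallers included Hdc, which makes histamine and is also in the enteroendocrine list (-2.09 ± 0.076), and the mast cell protease gene Cpa3 (-3.24 ± 0.51). On the log2(TPM + 1) scale the median was -1.11 and Cpa3 was at -1.74. The tight junction genes Ocln (-0.66 ± 0.067) and Tjp1 (-0.42 ± 0.056) fell, while their list of 20 was not called (5 rose and 10 fell, 16 adjusted over the list alone). The list's median was -0.50 (adjusted p = 0.587). The gastrin gene Gast fell (-0.70 ± 0.18). Further lists were not called, among them interferon response (12 rose and 6 fell of 23, 19 adjusted over the list alone; 0.46, adjusted p = 0.182), toll-like receptor and NF-kappaB signalling (4 and 7 of 22, 11 adjusted over the list alone; -0.12, 0.969), the interleukin 17 axis (1 and 0 of 7, 0 adjusted over the list alone; -0.059, 0.895) and antigen presentation (6 and 5 of 18, 11 adjusted over the list alone; 0.034, 0.895). The same held for markers of T and natural killer cells (0 and 2 of 9, 0 adjusted over the list alone; -0.86, 0.78), B and plasma cells (1 and 4 of 9, 5 adjusted over the list alone; -1.34, 0.453) and macrophages (0 and 2 of 14, 1 adjusted over the list alone; -0.16, 0.911). Xenobiotic and antioxidant genes (5 and 12 of 21, 17 adjusted over the list alone; -0.26, 0.587) and genes of apoptosis and p53 (5 and 5 of 19, 10 adjusted over the list alone; 0.059, 0.911) were not called either. Test and median differed in sign for the cytokine, interleukin 17 and enteric neuron lists, where the mean was also negative, and for the extracellular matrix list, while test and mean differed for the antigen presentation and apoptosis lists.

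With an estimated correlation 12 of the 16 calls held, all but surface mucous cells, the mitochondrial genome, the cell cycle, and mast cells and eosinophils. The calls that held then had camera adjusted p-values from 7.26e-05 (smooth muscle) to 0.0347 (parietal cells). At the preset correlation of 0.01 that of smooth muscle was 1.61e-57, so the very small camera p-values depend on the preset. The fry test, which asks whether the genes of a list move on balance, called 26 of the 32 lists. Quantile normalization moved the median of all genes by 0.15 in this comparison, and 1461 genes (217 higher, 1244 lower) passed a glmTreat test against a 2-fold change.

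**Figure D2:**
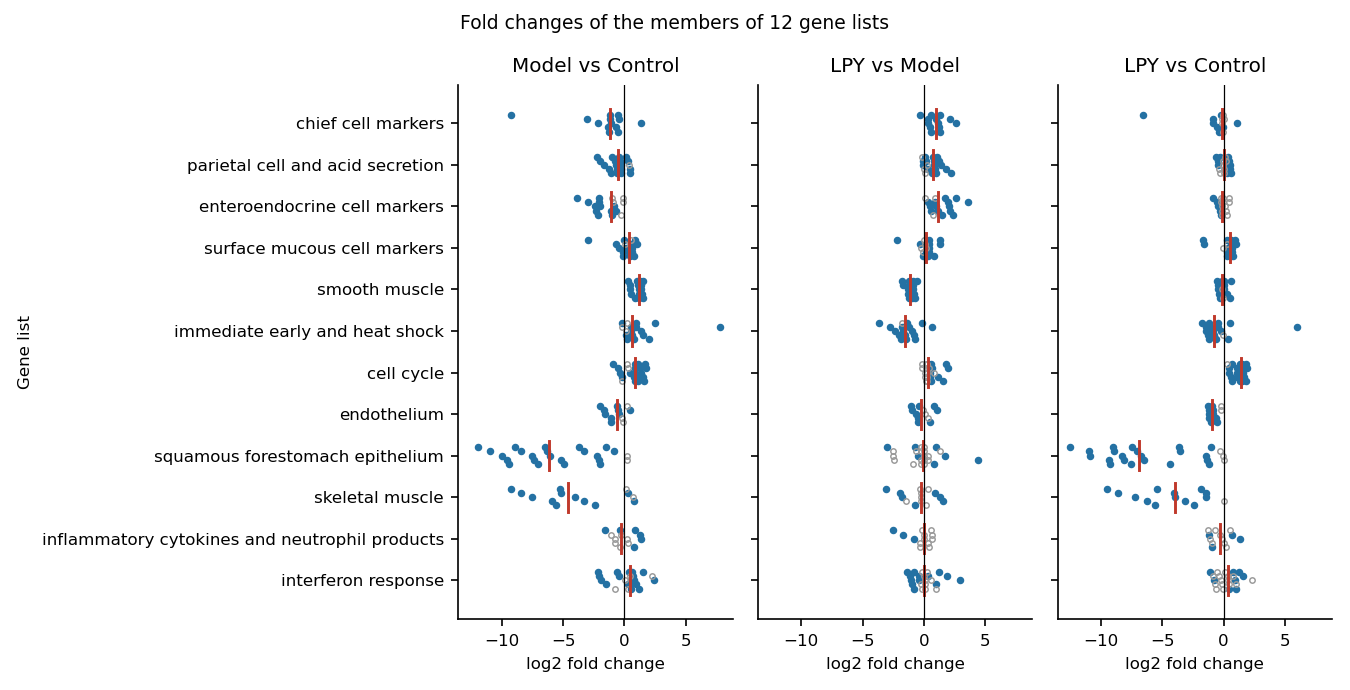
Log2 fold change of each member of 12 gene lists in the 3 comparisons, with filled blue points for called genes, open grey points for genes not called and a red line at the list's median. The smooth muscle median was 1.15 in Model against Control and -1.11 in LPY against Model, and the squamous median was -6.16 and -0.10.

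The comparison of LPY with Model asked what the decoction changed in the infected stomach. Chief cell and hormone genes were higher in LPY than in Model, and smooth muscle, immediate early and heat shock genes were lower. Pgc rose from 77920 ± 1721 to 150509 ± 369.7 CPM (0.95 ± 0.0081, adjusted p = 1.23e-44), Chga from 175 ± 2.38 to 579 ± 21.8 CPM (1.73 ± 0.032) and Dcn (ENSRNOG00000004554), which encodes the collagen-binding proteoglycan decorin, from 566 ± 3.13 to 2875 ± 18.5 CPM (2.34 ± 0.021). Hspa1b fell from 520.1 ± 12.3 to 40.6 ± 2.44 CPM (-3.68 ± 0.048) and Myh11 from 11193 ± 130.2 to 4814 ± 50 CPM (-1.22 ± 0.014). Ptgs2 fell to 5.97 ± 1.1 CPM (-1.68 ± 0.17).

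In total 8206 genes passed, 4180 higher and 4026 lower in LPY, and 2513 did so at 2-fold or more (1829 higher, 684 lower). With quantile normalization 3739 were higher and 4746 lower, and 1444 and 946 at 2-fold or more. Replicates did not overlap for 62.6% of genes, against 10% by chance if the libraries are independent samples. Most of the genes with the highest fold changes were listed at 0 in Model. The fetuin gene Ahsg (ENSRNOG00000038370) was at 7.65 ± 2.77 CPM in LPY and at least 145-fold higher than in Model. The fibrinogen chain genes Fgg, Fga and Fgb were at least 116, 80.5 and 64.9-fold higher, Pzp, Wfdc21 and Apoh at least 125, 77.6 and 73.4-fold, and the cytochrome P450 genes Cyp2c7 and Cyp3a2 at least 81.4 and 59.0-fold. Serpina3n and Serpina3c were at least 109 and 86.9-fold higher, but these, like the P450 genes, belong to families of similar copies among which reads can be split. The uroplakin gene Upk3b was 477-fold higher (95% counting interval 85.1 to 18884). A list of abundant hepatocyte genes was written after these genes were seen and holds none of them. It was prompted by these same libraries, so its p-values are not independent support. Of its 15 tested genes 12 rose and 1 fell (median 2.90, camera adjusted p = 2.30e-05, or 0.00498 with an estimated correlation), and the albumin gene Alb was at 122 CPM in LPY, 24.2 in Model and 28.8 in Control. Among the lowest were Fam180a (-4.97 ± 0.44), the heart transcription factor gene Nkx2-5 (-3.65 ± 0.77), Lgals5 (-3.58 ± 0.18), Myh6 (-3.39 ± 0.36), Itga2b (-3.22 ± 0.62), Plppr1 (-3.82 ± 0.82) and Togaram2 (-3.58 ± 0.82), and Ppp1r32 was at least 19.8-fold lower. Ccdc28b (-4.05 ± 0.75) was at -9.00 without LPY replicate 1, Hba-a3 (-3.28 ± 0.54), a globin gene with similar copies, was at -5.10 without LPY replicate 2, and Duoxa2 was 12.4-fold lower (95% counting interval 3.99 to 62.2), or -6.76 on the log2 scale without LPY replicate 2. On the log2(TPM + 1) scale Fam180a, Plppr1, Nkx2-5 and Myh6 were at -2.66, -1.65, -1.33 and -1.30.

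Of the 32 lists 13 were called. Of 13 chief cell markers 12 rose, such as Cym (2.62 ± 0.052), Chia (2.15 ± 0.029) and Cblif (1.27 ± 0.025), and Nkx6-3 fell (13 adjusted over the list alone). Their median was 0.95 (adjusted p = 4.43e-19). Of 17 enteroendocrine markers 14 rose and none fell (14 adjusted over the list alone). Their median was 1.11 (adjusted p = 5.4e-11), with Slc18a2 at 3.59 ± 0.11, Chgb at 2.38 ± 0.083 and Sst at 1.47 ± 0.054, and Gast rose by 1.11 ± 0.18. Of 20 parietal cell genes 14 rose and 2 fell (16 adjusted over the list alone). Their median was 0.70 (adjusted p = 1.35e-05). The carbonic anhydrase gene Car2 (0.93 ± 0.026), Aqp4 (1.76 ± 0.052) and the sodium-proton exchanger gene Slc9a4 (1.09 ± 0.054) rose and Kcnq1 fell (-0.11 ± 0.046). Atp4b fell (-0.063 ± 0.017) but was higher with quantile normalization (0.46), and its call was lost with limma without trend (adjusted p = 0.309; 1.18e-50 to 0.309 over its alternatives). It was at -0.042 among genes with a mean count of at least 50. Atp4a was at -0.027 ± 0.015 (adjusted p = 0.124) and higher with quantile normalization (0.084), and it passed without Model replicate 1 (adjusted p = 0.0397) or LPY replicate 1 (0.0352; 0.00652 to 0.77 over its alternatives). Muc5ac was at 0.032 ± 0.014 (adjusted p = 0.0547) but passed in 6 of 21 alternatives (2.69e-07 to 0.592), among them quantile normalization (0.33) and leaving out LPY replicate 3 (adjusted p = 0.0469). Tff1 fell (-0.36 ± 0.017) but was higher with quantile normalization (0.18), and Tff2 fell (-0.23 ± 0.027), a call lost with quantile normalization (-0.031, adjusted p = 0.191; 7.05e-26 to 0.191 over its alternatives). Surface mucous markers were not called (9 rose and 3 fell of 17, 13 adjusted over the list alone). Their median was 0.19 (adjusted p = 0.0817). Of 16 mucous neck, metaplasia and progenitor markers 9 rose and 4 fell (14 adjusted over the list alone). Their median was 0.32 (adjusted p = 0.0378), but the adjusted p was 0.112 with an estimated correlation. The call was lost in 8 of 21 alternatives (0.0164 to 0.263), and the median was 0.16 without Model replicate 3, 0.18 without LPY replicate 2, 0.20 in a fit of the compared groups alone and 0.21 on the log2(TPM + 1) scale. Pgc, shared with the chief cell list, the gland mucin gene Muc6 (2.01 ± 0.13) and A4gnt (1.38 ± 0.076), which modifies gland mucins, rose.

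All 16 smooth muscle genes fell (16 adjusted over the list alone). Their median was -1.11 (adjusted p = 1.78e-66), with Des at -1.25 ± 0.017 (-0.77 with quantile normalization) and Acta2 at -1.27 ± 0.019 (-0.53). The list summed to 24887 CPM in LPY. Of 17 immediate early and heat shock genes 15 fell, such as Jun (-2.08 ± 0.05), Hspb1 (-1.39 ± 0.053) and Zfp36 (-1.58 ± 0.063), and Klf4 rose (0.69 ± 0.046; 16 adjusted over the list alone). Their median was -1.58 (adjusted p = 3.49e-21). Of 20 unfolded protein response genes 15 rose, such as Hsp90b1 (1.21 ± 0.029) and Pdia3 (1.04 ± 0.031), and 4 fell, namely Herpud1, Atf4, Manf and Ddit3 (19 adjusted over the list alone). Their median was 0.38 (adjusted p = 0.000181), and the adjusted p was 0.0625 with an estimated correlation (0.000131 to 0.0625 over its alternatives). Of 31 nuclear electron transport genes 23 fell and 3, Uqcrc2 (0.88 ± 0.039), Ndufs1 and Atp5pb, rose (26 adjusted over the list alone). Their median was -0.22 (adjusted p = 0.00788), but the adjusted p was 0.0595 with an estimated correlation and 0.216 with quantile normalization (6.2e-05 to 0.216 over all alternatives), where the median was -0.12. Cox4i1 fell (-0.64 ± 0.03), and Atp5f1b fell (-0.35 ± 0.019) but was higher with quantile normalization (0.33). The mitochondrial genome list was not called (6 rose and 6 fell of 13, 12 adjusted over the list alone). Its median was 0.022 (adjusted p = 0.603).

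Of 17 extracellular matrix and fibroblast genes 10 fell, such as Col6a1 (-1.15 ± 0.039) and Fn1 (-1.09 ± 0.038), and 4 rose, Dcn by the most (15 adjusted over the list alone). Their median was -0.71 (adjusted p = 0.00304), and the adjusted p was 0.112 with an estimated correlation (0.000356 to 0.112 over its alternatives). Of 14 adipocyte genes 10 fell, such as Plin4 (-1.37 ± 0.054), and Lpl rose (0.88 ± 0.036; 11 adjusted over the list alone). Their median was -0.47 (adjusted p = 0.0382), and the adjusted p was 0.112 with an estimated correlation and 0.0585 among genes with a mean count of at least 50 (0.00436 to 0.112 over all alternatives). Of 6 erythrocyte genes 3 fell, with the globin genes Hba-a1 (-2.19 ± 0.048) and Hbb (-1.56 ± 0.055) among them, and Hemgn rose (2.29 ± 0.74; 4 adjusted over the list alone). Their median was -0.99 (adjusted p = 0.000181). That call was lost in 4 of 17 alternatives (adjusted p 5.03e-05 to 0.125), among them quantile normalization (0.0786) and a replicate block (0.0948). The Hemgn call was lost without Model replicate 1 (adjusted p = 0.0552; 0.00356 to 0.0552 over its alternatives), and Hemgn was at 1.53 with quantile normalization. Of 17 pancreatic acinar genes 8 rose, such as Cel (3.14 ± 0.12), and Ctrl fell (9 adjusted over the list alone). Their median was 0.61 (adjusted p = 0.00984), and the adjusted p was 0.0849 with an estimated correlation (0.00567 to 0.0849 over its alternatives). The median was 0.38 and 0.37 without LPY replicates 1 and 2, 0.96 without Model replicate 1, 0.32 with quantile normalization and 0.37 on the log2(TPM + 1) scale. Of 10 mast cell and eosinophil markers 8 rose (10 adjusted over the list alone). Their median was 1.52 (adjusted p = 0.0378), with Hdc, shared with the enteroendocrine list, at 1.92 ± 0.077 and Cpa3 at 3.22 ± 0.51. The adjusted p was 0.171 with an estimated correlation (0.00383 to 0.171 over the alternatives). The median was 1.01 with quantile normalization and 0.78 on the log2(TPM + 1) scale, where Cpa3 was at 1.60.

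Squamous genes (4 rose and 3 fell of 24, 6 adjusted over the list alone; median -0.10, adjusted p = 0.928) and skeletal muscle genes (3 and 4 of 14, 7 adjusted over the list alone; -0.24, 0.28) were not called, and their genes summed to 68.2 and 80.03 CPM in LPY. Of the cytokine and neutrophil genes Ptgs2, Nfkbia and Lcn2 fell and none of the 13 rose (3 adjusted over the list alone). Their median was -0.043 (adjusted p = 0.479). Il1b was at 0.61 ± 0.63 (adjusted p = 0.423; -0.019 with quantile normalization) and Cxcl1 at 0.36 ± 0.95 (adjusted p = 0.768; -0.16 with quantile normalization), Cxcl1 at -0.29 without Model replicate 1 and -0.73 without LPY replicate 3. Ocln (0.98 ± 0.067) and Tjp1 (0.40 ± 0.056) rose, and of 20 tight junction and adhesion genes 11 rose and none fell, while the list was not called (11 adjusted over the list alone). The list's median was 0.37 (adjusted p = 0.13). Of 22 cell cycle genes 9 rose and none fell (8 adjusted over the list alone). Their median was 0.32 (adjusted p = 0.066). The remaining lists had adjusted p-values from 0.0817 (intestinal epithelium) to 0.928 (T and natural killer cells), and test and median differed in sign for the interleukin 17 and interferon lists. With an estimated correlation 6 calls held, those of smooth muscle, immediate early and heat shock genes, chief cells, enteroendocrine cells, parietal cells and erythrocytes, and fry called 28 lists. Those 6 calls then had camera adjusted p-values from 4.71e-05 (smooth muscle) to 0.0405 (erythrocytes). Quantile normalization moved the median of all genes by -0.10, and 1269 genes (998 higher, 271 lower) passed the glmTreat test.

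Whether LPY rats lay nearer to Control than Model rats did was asked gene by gene. Of the 4181 genes higher in Model than in Control, 3045 were lower in LPY than in Model and 105 were higher still, and 2623 were not called between LPY and Control. Of the 4428 genes lower in Model, 3387 were higher in LPY than in Model and 123 were lower still, and 2944 were not called between LPY and Control. The 2157 genes lower by 2-fold or more in Model had a median log2 fold change of -1.59 against Control in Model and -0.20 in LPY, and 651 of them were still lower in LPY than in Control. The 562 genes higher by 2-fold or more in Model had medians of 1.32 in Model and 0.47 in LPY, and 221 of them were still higher in LPY than in Control. Both sets were picked for a difference in Model. Anything that set only the Model libraries apart thus also brings the LPY medians nearer to Control. Of all 4181 higher genes 479 were lower in LPY than in Control, and of all 4428 lower genes 419 were higher. Opposite calls expected from independent lists numbered 1184 for the higher genes and 1302 for the lower ones, counts that ignore the Model group shared by both comparisons. Across 14211 genes, which are not independent replicates, the log2 fold changes of Model against Control and LPY against Model correlated at r = -0.616 (Spearman rho -0.760). Both comparisons contain the Model libraries, and 20 simulations of unchanged groups gave r = -0.449 and rho -0.403 from that alone. The covariance was -0.722 against -0.0288 in the simulations, a difference of -0.694. The simulated groups held no differences, so their r is not a share of the observed r. Noise of the shared libraries gave only a small covariance. The simulations hold the spread between these libraries alone. Anything else that set all Model libraries apart enters both comparisons, and the 3 libraries could not be split into separate pairs. Part of the excess of opposite calls may come from that. Across genes the log2 fold change also correlated with effective length, at a Spearman rho of -0.193 in Model against Control, 0.191 in LPY against Model and -0.0218 in LPY against Control. With an offset for effective length, added after seeing the data, these were 0.0224, -0.00767 and 0.0125. The correlation between Model against Control and LPY against Model was then r = -0.611 (rho -0.756), 3213 of 4351 genes higher in Model were lower in LPY than in Model, and 3116 of 4131 lower ones were higher. Tissue layers also set Model apart, with smooth muscle genes summing to 23649 CPM in Control, 53857 in Model and 24887 in LPY. Mesothelial genes had medians of -3.77 in Model against Control and 3.89 in LPY against Model. Squamous genes, at 678, 55.2 and 68.2 CPM, did not return. Whether differently sampled Model tissue gave part of the opposite changes was not tested.

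**Figure D3:**
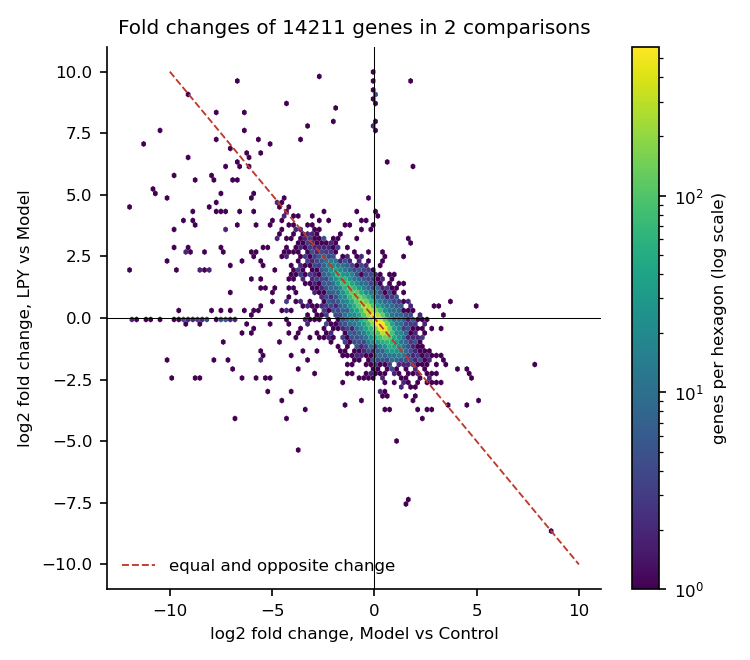
Log2 fold change of 14211 genes in LPY against Model (vertical axis) and Model against Control (horizontal axis), with the colour of each hexagon giving its number of genes on a log scale and a dashed line where both changes are equal and opposite. The cloud runs downward to the right (r = -0.616), where unchanged groups that share the Model libraries gave -0.449. The covariance was -0.722, against -0.0288 in the unchanged groups.

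The comparison of LPY with Control asked what still set treated, infected rats apart from untouched ones. Cell cycle and mucous genes were higher in LPY, and genes of squamous epithelium, skeletal muscle, endothelium and red blood cells were lower. The proliferation marker Mki67 rose from 30.4 ± 1.72 to 82.3 ± 1.61 CPM (1.44 ± 0.084) and Muc5ac from 3204 ± 11 to 5986 ± 38.2 CPM (0.90 ± 0.015). Cym fell from 3678 ± 58 to 37.6 ± 1.92 CPM (-6.61 ± 0.033), and the globin gene Hba-a1 from 300.1 ± 3.34 to 53.7 ± 3.2 CPM (-2.48 ± 0.048). Ptgs2 was lower in LPY than in Control (-0.92 ± 0.18).

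In total 4033 genes passed the edgeR test, 1988 higher and 2045 lower, and 925 did so at 2-fold or more (313 higher, 612 lower). The split of all calls was 1064 higher and 2755 lower with limma on log2(TPM + 1), and that at 2-fold or more was 445 and 554 with quantile normalization. Replicates did not overlap for 40.1% of genes, against 10% by chance if the libraries are independent samples. The genes with the highest fold changes were listed at 0 in Control. Of the 15 genes of the hepatocyte list, written after results had been seen, 11 rose and none fell (median 2.09, camera adjusted p = 1.52e-08, or 0.00118 with an estimated correlation). Ahsg, Fga, Fgb and Apoh were at least 119, 66.1, 53.3 and 60.2-fold higher, and Cyp2c7, Cyp3a2, Sult2a2, Serpina3n and Serpina3c, all of families with similar copies, at least 66.8, 48.5, 25.6, 89.7 and 71.3-fold. Rup2 was at least 28.4-fold higher. Of the lowest genes, Krt5 (ENSRNOG00000050420), a keratin of basal squamous cells, was at least 661-fold lower, and Stfa3, Serpinb3a, the muscle genes Myl3 and Actc1, Mt4, Sprr3 and C18h5orf46 were at least 408, 351, 259, 219.5, 249, 231 and 163-fold lower. Lgals7 was 2564-fold lower (95% counting interval 459.8 to 101310), and Myh8 was at -9.97 ± 0.24 (-4.69 on the log2(TPM + 1) scale).

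Of the 32 lists 17 were called. Of 22 cell cycle genes 21 rose and none fell (21 adjusted over the list alone). Their median was 1.38 (adjusted p = 1.04e-16), with the cyclin gene Ccna2 at 1.87 ± 0.13, Rrm2 at 1.58 ± 0.11 and the topoisomerase gene Top2a at 1.47 ± 0.11. Of 17 surface mucous markers 13 rose and 2 fell (15 adjusted over the list alone). Their median was 0.51 (adjusted p = 1.12e-15), with Gkn2 at 0.60 ± 0.016 (0.24 with quantile normalization) and Tff1 at 0.64 ± 0.018. Tff2, of the mucous neck list, was at 0.65 ± 0.028. Of 13 chief cell markers 7 fell and Nkx6-3 rose (8 adjusted over the list alone). Their median was -0.12 (adjusted p = 2.55e-31), with Chia at -0.87 ± 0.027 and Cblif at -0.85 ± 0.025, and the median was -0.20 without LPY replicate 2 and -0.21 on the log2(TPM + 1) scale. Pgc fell (-0.20 ± 0.008), by 0.30 on the log2(TPM + 1) scale. Quantile normalization set it to 0.00, as it does any gene of equal rank in both groups, so that lost call was built in. Of 20 parietal cell genes 8 rose and 4 fell (12 adjusted over the list alone). Their median was 0.056 (adjusted p = 0.0384), but the adjusted p was 0.0887 with an estimated correlation. The call was lost in 9 of 21 alternatives (0.0181 to 0.75), among them leaving out Control replicate 3 (0.0676), where the median was -0.0098. The median was 0.13 without Control replicate 1, 0.18 without LPY replicate 2, -0.027 without LPY replicate 3, -0.035 on the log2(TPM + 1) scale, 0.024 with quantile normalization and 0.0061 among genes with a mean count of at least 50. Car2 rose by 0.61 ± 0.026, and Atp4a rose by 0.39 ± 0.015 but was lower with quantile normalization (-0.050). Atp4b rose by 0.26 ± 0.017 (0.15 on the log2(TPM + 1) scale), and quantile normalization set it to 0.00 through equal ranks, as it did Pgc. Of 16 mucous neck, metaplasia and progenitor markers 6 rose and 4 fell (10 adjusted over the list alone). Their median was 0.09 (adjusted p = 0.0384), and the adjusted p was 0.0887 with an estimated correlation. The call was lost in 8 of 21 alternatives (0.0266 to 0.175), among them leaving out Control replicate 3 (0.0676), where the median was 0.060. The median was 0.17 without Control replicate 2, 0.055 without LPY replicate 3 and -0.0035 on the log2(TPM + 1) scale (adjusted p = 0.0926). Enteroendocrine markers were not called (0 rose and 5 fell of 17, 6 adjusted over the list alone). Their median was -0.17 (adjusted p = 0.125), and Gast was at 0.41 ± 0.18 (adjusted p = 0.0793) but passed in 4 of 21 alternatives (0.0327 to 0.293), among them leaving out LPY replicate 2 (0.0423).

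Of 24 squamous genes 21 fell (21 adjusted over the list alone). Their median was -6.89, or -5.07 with genes at 0 set to their bound (adjusted p = 1.87e-55), with Krt10 at -6.75 ± 0.13. Of 14 skeletal muscle genes 13 fell (13 adjusted over the list alone). Their median was -4.00 (adjusted p = 4.93e-39), with Acta1 at -3.14 ± 0.079. On the log2(TPM + 1) scale these medians were -1.73 and -1.94. Of 17 intestinal genes 16 fell, such as the alkaline phosphatase gene Alpi (-5.64 ± 0.35; -3.50 on the log2(TPM + 1) scale) and Reg3g (-3.54 ± 0.15), and Clca1 rose (3.26 ± 0.052; 17 adjusted over the list alone). Their median was -2.63 (adjusted p = 9.13e-11), or -1.63 among genes with a mean count of at least 50. Of 17 pancreatic acinar genes 11 fell and 2 rose (13 adjusted over the list alone). Their median was -0.98 (adjusted p = 5.64e-05), with Ctrb1 at -0.98 ± 0.074, and the median was -0.38 among genes with a mean count of at least 50. Of 12 endothelial genes 10 fell (11 adjusted over the list alone). Their median was -0.92 (adjusted p = 8.92e-07). Fallers included Plvap (-0.97 ± 0.088), Pecam1 (-0.88 ± 0.085) and the growth factor receptor gene Kdr (-1.16 ± 0.15). Of 6 erythrocyte genes 3 fell (3 adjusted over the list alone). Their median was -1.21 (adjusted p = 1.32e-16), with Hbb at -2.17 ± 0.055, and the median was -2.32 without a filter on low counts. Of 17 extracellular matrix and fibroblast genes 12 fell, such as the metalloprotease gene Mmp2 (-1.17 ± 0.076), and Dcn rose (14 adjusted over the list alone). Their median was -0.19 (adjusted p = 0.000303), with a median of -0.29 in limma on log2(TPM + 0.5) and log2(TPM + 0.1). The Dcn call (0.24 ± 0.02) was lost with quantile normalization (0.060, adjusted p = 0.449; 1.45e-39 to 0.449 over its alternatives), and Dcn was at 0.13 on the log2(TPM + 1) scale. Of 14 adipocyte genes 7 rose, such as Adipoq (1.29 ± 0.066), and 2 fell (10 adjusted over the list alone). Their median was 0.49 (adjusted p = 2.41e-05), and the median was 0.28 on the log2(TPM + 1) scale. Smooth muscle genes were not called as a list (6 rose and 8 fell of 16, 14 adjusted over the list alone). Their median was -0.12 (adjusted p = 0.528).

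All 13 genes of the mitochondrial genome rose (13 adjusted over the list alone). Their median was 0.68 (adjusted p = 1.62e-52, or 0.00436 with an estimated correlation, which was 0.628), or 0.38 with quantile normalization. Mt-nd2 was at 1.02 ± 0.018 (0.38 with quantile normalization). Mt-co1 was at 0.68 ± 0.0088, and quantile normalization set it to 0.00, as it does any gene of equal rank in both groups. Of 31 nuclear electron transport genes 21 rose and none fell (22 adjusted over the list alone). Their median was 0.20 (adjusted p = 8.62e-07), and the median was 0.095 on the log2(TPM + 1) scale. Of 17 immediate early and heat shock genes 13 fell, such as Hspa1b (-1.16 ± 0.05), Jun (-1.14 ± 0.051) and Zfp36 (-1.42 ± 0.064), and 3 rose (16 adjusted over the list alone). The highest member was at 5.99. Their median was -0.81 (adjusted p = 9.84e-12). Of 20 unfolded protein response genes 7 fell, such as Herpud1 (-1.51 ± 0.049), and 5 rose, such as Calr (0.36 ± 0.031; 12 adjusted over the list alone). Their median was -0.10 (adjusted p = 0.0481). That call was lost in 14 of 21 alternatives (adjusted p 0.0294 to 0.187), among them an estimated correlation (adjusted p = 0.187), a replicate block (0.111), and leaving out Control replicate 1 (0.0629), Model replicate 1 (0.0504), LPY replicate 1 (0.0534) or LPY replicate 2 (0.0629). The median was -0.20 on the log2(TPM + 1) scale (adjusted p = 0.140). Cytokine and neutrophil genes were not called as a list (2 rose and 2 fell of 13, 5 adjusted over the list alone). Their median was -0.32 (adjusted p = 0.453), with Il1b at -0.96 ± 0.58 (adjusted p = 0.247) and Cxcl1 at -0.73 ± 0.89 (adjusted p = 0.606). Ocln rose by 0.32 ± 0.065, a call lost with limma on log2(TPM + 0.5) and log2(TPM + 0.1) (adjusted p = 0.0501 and 0.0523; 1.9e-06 to 0.0523 over its alternatives), and Tjp1 was at -0.016 ± 0.056 (adjusted p = 0.876). The other lists had adjusted p-values from 0.157 (tight junction and adhesion) to 0.983 (interleukin 17), and test and median or mean differed in sign for the interleukin 17, antigen presentation and tight junction lists. With an estimated correlation 14 calls held, all but parietal cells, mucous neck cells and the unfolded protein response, and fry called 27 lists. Those 14 calls then had camera adjusted p-values from 0.000126 (squamous and skeletal muscle genes) to 0.0494 (extracellular matrix and fibroblast genes). The glmTreat test passed 364 genes (92 higher, 272 lower). The log2 fold changes of LPY and Model, each against Control, correlated at r = 0.613 across genes (rho 0.312), where unchanged groups sharing the Control libraries gave 0.517 (rho 0.464), and the covariance was 0.717 against 0.0346, a difference of 0.683.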

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

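The alternatives added after seeing the data were limma on log2(TPM + 1), the counts at 2-fold or more, the glmTreat test, the offset for effective length and the medians of the called lists. The planned pseudocounts of 0.5 and 0.1 were tried on the limma fit of TPM, because the count test has none. The numbers of genes called over all genes stayed within 1.5 times of those reported under every alternative run, and so did the numbers of lists except in LPY against Model, where 6 of 13 calls held with an estimated correlation. For the named genes, 1984 values in Model against Control kept their direction and their side of the threshold under an alternative, 7 lost the call and 3 reversed. In LPY against Model 1725 kept both, 3 lost the call, 9 gained it and 8 reversed, and in LPY against Control 1958 kept both, 7 lost it, 4 gained it and 1 reversed. Of the called lists' tests under the alternatives, 11, 20 and 31 lost the call in these comparisons, 14 of them with an estimated correlation, and 1 reversed. The count of genes at 2-fold or more was 1806, 1499 and 533 with limma on log2(TPM + 1), a scale that shrinks changes of low genes, and 1461, 1269 and 364 with glmTreat, which asks for more than a 2-fold change. Among genes with a mean count of at least 50, fewer of which are tested, it was 502 in LPY against Control.

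The correlation between Model against Control and LPY against Model was -0.732, -0.710 and -0.664 with limma on TPM at pseudocounts of 1, 0.5 and 0.1, -0.532 without a filter, -0.714 among genes with a mean count of at least 50 and -0.578 with quantile normalization. It lay between -0.640 without Model replicate 1 and -0.570 without LPY replicate 2, and was -0.611 with the offset for effective length.

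Quantile normalization, which forces all libraries to a single distribution and so sets a gene of equal rank in 2 groups to a difference of 0, moved the median of all genes by 0.15 in Model against Control and -0.10 in LPY against Model. It turned the surface mucous list in Model against Control downward by its test (median 0.095), and reversed Atp4a (-0.13), Atp4b (-0.46) and Gkn2 (-0.38) there. In LPY against Model it reversed Tff1 (0.18), Atp4b (0.46), Atp4a (0.084), Il1b (-0.019), Cxcl1 (-0.16) and Atp5f1b (0.33), and in LPY against Control Atp4a (-0.050). In LPY against Control it set Pgc, Atp4b, Mt-co1 and Mt-nd4 to exactly 0, so those lost calls follow from the method. For the other single genes and for lists the cause was not tested. Cxcl1 in LPY against Model, not called, lay between -0.73 without LPY replicate 3 and 0.95 without LPY replicate 2, and was at -0.29 without Model replicate 1. The split of calls at 2-fold or more, higher against lower, became 1063 to 1609 in Model against Control, 1444 to 946 in LPY against Model and 445 to 554 in LPY against Control with quantile normalization, where 562 to 2157, 1829 to 684 and 313 to 612 were reported. With limma on TPM all calls in LPY against Control split 1064 to 2755, 1060 to 2732 and 1032 to 2645 at pseudocounts of 1, 0.5 and 0.1, where 1988 to 2045 were reported.

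The groups share replicate numbers, but nothing in the labels says that a number marks a shared litter, batch or day. Deviations of libraries with the same number correlated at -0.0398 to 0.0310, and those with different numbers at -0.0322 to 0.0225. For 0 of the 9 libraries did both closest libraries of the other groups carry its own number. With the replicate number as a replicate block, 8496, 8135 and 3925 genes and 16, 13 and 16 lists were called, and 4 list calls were lost. At these depths 3 counts, a floor chosen here, equal 0.132 to 0.209 CPM in a library, so lower levels rest on very few counts. Tnf, Il6 and Nos2 fell under the filter on low counts.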

Other observations

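Lists for the circadian clock, mesothelium, hepatocytes and glucocorticoid-responsive genes, the pathway test, the tests of the spread between libraries, of the tissue genes and of the splits of the libraries were chosen after results had been seen, and so were the genes named for these lists. Of 19 circadian clock genes 13 fell and 3 rose in Model against Control (median -0.68, camera adjusted p = 0.0017, or 0.0248 with an estimated correlation), and 12 fell and 3 rose in LPY against Control (median -0.90, adjusted p = 3.02e-13, or 0.000398). Dbp, a clock output gene, was at -2.24 ± 0.066 in Model and -2.43 ± 0.068 in LPY against Control, and Bmal1, which peaks opposite to it, at 2.06 ± 0.13 and 1.91 ± 0.14. In LPY against Model the list was not called (adjusted p = 0.342). Sampling times are not given in the sources used here. Of 11 glucocorticoid-responsive genes 10 fell in LPY against Control (median -1.47, adjusted p = 1.64e-45, or 2.21e-05 with an estimated correlation) and all 11 fell in LPY against Model (median -0.90, adjusted p = 9.36e-10, or 0.00223), with Per1, which the clock list also holds, at -2.44 ± 0.084 and Fkbp5 at -1.27 ± 0.038 against Control. In Model against Control 7 of them fell and 2 rose and the list was not called (median -0.21, adjusted p = 0.0541, or 0.125 with an estimated correlation). The hepatocyte list was not called there either (2 rose and 5 fell of 15, median -0.26, adjusted p = 0.401).

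Mesothelial genes, which mark the outer lining of abdominal organs, were lower in Model than in both other groups. Of 12 such genes 10 fell in Model against Control (median -3.77, adjusted p = 6.48e-05, or 0.0157 with an estimated correlation) and 11 rose in LPY against Model (median 3.89, adjusted p = 1.94e-06, or 0.00418), with Msln at -7.05 ± 0.30 and 6.98 ± 0.31. In LPY against Control 1 rose and 1 fell (adjusted p = 0.534). Of 323 KEGG pathways camera called 31 in Model against Control, 16 in LPY against Model and 38 in LPY against Control. With an estimated correlation camera called 0 in each, and 45, 46 and 61 had an unadjusted p under 0.05. Of 110 oxidative phosphorylation genes 85 rose and 9 fell in Model against Control (adjusted p = 2.60e-13, or 0.0785 with an estimated correlation) and 58 rose and 3 fell in LPY against Control (3.32e-14, or 0.0553). Of 121 ribosome genes 86 fell and 7 rose in LPY against Model (9.07e-12, or 0.175), and of 58 complement and coagulation genes 31 rose and 10 fell (0.0113, or 0.175).

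Between the libraries of a group, the variance of a gene was 3.53 to 4.05 times its mean count up to 3000 counts. Differences of at least 10% between the libraries of a group, as separate animals could give, were argued against for the typical gene. The variation beyond that multiple, from the median over genes, reached a CV of 1.46% at 3000 to 10000 counts and 1.81% above, both in Model. Single genes can vary more. If the libraries of a group share RNA, this spread says nothing about differences between animals. Repeat libraries of 1 RNA pool per group are a candidate explanation: 29 squamous and skeletal muscle genes, which tissue dissected from separate animals could hold in unequal amounts, varied between Control libraries at 0.804 of the ratio of genes of like count (highest 6.47). Differences between animals of any size stay open if RNA was shared, and smaller ones stay open otherwise. The origin of the constant multiple stays open too. A test on immunoglobulin variable genes was set first and was void, because 0 of the 8 such genes had enough counts.

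Genes of neighbouring tissues and tissue layers differed between the groups, with squamous genes at 678 CPM in Control, 55.2 in Model and 68.2 in LPY, smooth muscle genes at 23649, 53857 and 24887, and hepatocyte genes higher in LPY. A lower share of epithelium in Model that raised every other cell type alike was argued against, since the endothelial median was -0.60 (-0.69 to -0.56 over libraries) while that of smooth muscle was 1.15. The fibroblast and enteric neuron medians were -0.015 and -0.27, and that of adipocytes was 1.04. A lower share of epithelium with unequal changes of the other cell types was not tested and stays open. Tissue other than glandular mucosa in the Control libraries may account for part of it: of 29 squamous and skeletal muscle genes at 5 CPM or more in Control, 65.5% were at least 4-fold lower in both other groups, between the bounds set for and against it, with Krt10 at 186 CPM in Control, 2.95 in Model and 1.73 in LPY, Acta1 at 146, 14.5 and 16.6, but Ckm at 63.0, 79.0 and 23.4, and no gene of these lists in another list. An effect of infection on these genes cannot be told apart from it, because both infected groups were low in most of them (median ratio of LPY to Control 0.0490) and no uninfected treated group was analysed here. Liver tissue in the LPY libraries stays open as well, as does an untested effect of the decoction, since 10 of 17 hepatocyte genes (58.8%), or 10 of the 15 tested, were higher in LPY than in both other groups, again between the bounds, and the untested Apoa2 and Orm1 had 34 and 20 counts in LPY and 0 in the other groups.

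More genes were lower than higher by at least 2-fold in Model than in Control (2157 and 562). Loss of long transcripts as the whole cause was argued against, since the ratio of lower to higher genes was still 3.01 with effective length as an offset. A part played by length stays open, because the fold change correlated with effective length across genes at a Spearman rho of -0.193, between the bounds set before the result was seen. Scaling of the libraries also stays open, because the ratio was 3.88 with DESeq2 size factors and 1.51 with quantile normalization, while limma on log2(TPM + 1) went the other way, with 1576 lower and 230 higher genes. A change in infected mucosa itself stays open too and was not tested.

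Each comparison allows 10 splits of its 6 libraries into groups of 3, so that no share under 0.05 can be reached. In each of the comparisons 1 of 10 splits, the real one, gave as many genes, genes at 2-fold or more, or lists. Every other split mixes libraries of both groups, so where the groups differ, that difference widens the spread and lowers the calls. Fewer gene calls in the other splits were thus built in and say nothing about chance. In Model against Control the real split gave 8609 genes, 2719 at 2-fold and 16 lists, and the highest other split 0, 0 and 15. The numbers were 8206, 2513 and 13 against 0, 0 and 9 in LPY against Model, and 4033, 925 and 17 against 0, 0 and 13 in LPY against Control. List calls thus dropped far less than gene calls, so the number of lists called says little about the grouping. At an unadjusted p under 0.05 edgeR counted at most 225, 257 and 400 genes in the other splits, where the real ones gave 9097, 8743 and 5305.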
